A study of Mus musculus and Homo sapiens with 94 samples.

How the data were processed

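Gene expression was measured by RNA sequencing in 18 mouse libraries, from mice 8 to 10 weeks old per the labels' protocols. The 6 cerebellar libraries came from C57BL/6 mice and fall into 3 groups of 2: whole cerebellar homogenate, nuclei that stained for NeuN (NeuN+) and nuclei that did not (NeuN-). NeuN is an antigen of most neuronal nuclei. The 12 cortical libraries came from NeuN+ nuclei of the frontal cortex of mice given clozapine, an antipsychotic drug, or vehicle. Each cortical treatment has 3 numbered samples and each numbered sample has 2 libraries. The labels name 129S6/SvEv mice for the cortex, while their protocol text writes the strain another way. Per the labels' protocols, nuclei were stained with a fluorescent antibody against NeuN and sorted by flow cytometry. Cerebellar nuclei were first spun through a sucrose cushion, and cortical nuclei in iodixanol. The dose and duration of the treatment are not given in the sources used here. The series holds 94 samples. The other 76, which profile DNA methylation by reduced representation bisulfite sequencing in the same tissues, in the human lymphoblastoid cell line GM12878 and in controls, were not analysed here.

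The deposited values are FPKM (fragments per kilobase of transcript and per 1e6 mapped fragments), made by the authors per library and laid out as a Cufflinks gene table per the file headers. Reads had been aligned with TopHat2 2.1.1 and Bowtie 1.1.1, per the submitters' processing notes, which name Cufflinks without a version. The notes list the mouse build mm9 beside a human build, and loci are given here in mm9 coordinates as the files state them, with starts counted from 1. The annotation, the handling of strand and any filter are not given in the sources used here. A locus in the files is the span of the gene, and carries no exon or UTR annotation. The deposited tables hold 24854 entries, or 24318 gene symbols. Malat1 was listed at 0 in the 6 cerebellar libraries, each with a status marking too much data to estimate, so its cerebellar level is unknown. The 13 mitochondrially encoded genes had no entry under the symbols searched.

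An FPKM value does not hold its read count. The confidence bounds that the authors' Cufflinks run wrote beside each FPKM imply 7.62 to 11.8 M fragments (M, 1e6) per library in the cerebellum and 7.79 to 12.1 M in the cortex. Whole fragments were not recovered: in the 18 libraries, 44.7 to 54.4% of values resting on 20 or fewer implied fragments lay within 0.02 of a whole number. The precision therefore rests on the spread between libraries. That spread was checked against counting error as the ratio of the observed SD of log2 differences between 2 libraries to the SD their implied fragments would give, over genes with at least 20 fragments in each.

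Entries with one symbol were summed. Short RNA genes, chosen by symbol (microRNA, small nucleolar, small nuclear and similar), were left out because an FPKM divides by a length shorter than a fragment. Libraries of one region were scaled by the median ratio to the geometric mean of each gene, over genes at 1 FPKM or more in each library. Genes with a scaled FPKM of at least 1 in 2 or more cerebellar libraries, or in 3 or more averaged cortical values, were tested. Values were log2(scaled FPKM + 1), so a fold change on this scale understates the change of low genes. The 2 cortical libraries of a number were averaged on the log2 scale and counted as 1 sample, giving n = 3 against 3.

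Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean trend, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 3 cerebellar groups shared 1 fit of 6 libraries, and the cortex was fitted apart. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. camera was run again with an estimated correlation, and fry tested whether the genes of a list moved on balance in one direction. The run with an estimated correlation had little power, with 3 residual degrees of freedom in the cerebellum and 4 in the cortex. A list that failed in it may still differ. Lists with at least 3 tested members entered, 23 in the cerebellum and 32 in the cortex. Means are given ± SD of scaled FPKM. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

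The designs, the 38 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. The anchor genes of the rule include Rbfox3, Gabra6, Pcp2, Slc1a3, Mbp and Malat1 in the cerebellum, and Rbfox3, Htr2a, Drd2, Grm2, Hdac2 and Dnmt3a in the cortex. It adds up to 4 members of each list with the greatest absolute log2 fold change among those past the threshold, or, where none passes, the 4 with the highest level, as values. For each comparison and direction it adds the 8 genes with the greatest absolute log2 fold change past the threshold, at 5 FPKM or more in the higher group and with groups that do not overlap. Where fewer than 10 genes pass, it adds the 10 genes with the smallest p. Some genes it names are short RNA that the symbol rule missed, and these were left out in an alternative added after the data were seen (genes with a locus under 200 bases).

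The fits were tested on simulated data, in which 200 genes were changed by a known amount. These were drawn from genes with a mean above 2 on the log2 scale, so recovery of lower genes was not tested. For NeuN+ against NeuN- nuclei (13451 genes), 66.5% were recovered at a log2 change of 0.5, with 7 false calls, and 96.5% at 1, with 8. For clozapine against vehicle (12570 genes), 0% were recovered at 0.5, with 0 false calls, and 55% at 1, with 5. A shift of 0.5 in the astrocyte list was found in both simulations, with 0 other lists called. The noise was drawn for each gene apart, on values already scaled. The simulations therefore test neither the scaling nor lists whose genes vary together. In the cortex the ribosomal protein list had an estimated correlation of 0.91. The labels do not say that the 2 libraries of a cerebellar group came from separate animals, so p-values measure the spread between these libraries, which may be technical. That spread was 1.13 to 1.34 times counting error, below the 1.37 to 1.60 times between 2 libraries of one cortical number. In the cerebellum n = 2 therefore counts libraries, and SDs and p-values may hold no spread between animals. Alternatives changed the scaling, pseudocount, filter, variance prior, short RNA rule, entries with a failed status, replicate block, groups in the fit, treatment of paired cortical libraries and list test, and left out each sample in turn.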

Results

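RNA was sequenced from 3 kinds of cerebellar material, with 2 libraries each, and from NeuN+ nuclei of frontal cortex, with 3 numbered samples given clozapine and 3 given vehicle and 2 libraries per number. The cerebellar libraries held an implied 7.62 to 11.8 M fragments (M, 1e6) and the cortical libraries 7.79 to 12.1 M. Between 10547 and 12757 genes reached 1 FPKM in a library. Cerebellar libraries of one group agreed closely (Pearson r across 13451 genes, 0.997 to 0.998; genes are not independent replicates), and libraries of different groups had r from 0.656 to 0.846. The SD of log2 differences was 1.13 to 1.34 times counting error within a cerebellar group and 9.34 to 12.9 times between groups. In the cortex, the 2 libraries of a number differed by 1.37 to 1.60 times counting error, more than cerebellar libraries of one group did. The cerebellar SDs and p-values below may thus hold no spread between animals. Numbers of one treatment differed by 1.80 to 2.98 times where clozapine number 1 was not involved and by 3.86 to 4.99 times where it was. Across 12468 genes, r was 0.993 to 0.995 within a cortical number, 0.953 to 0.993 within a treatment and 0.949 to 0.992 between treatments.

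NeuN+ and NeuN- cerebellar nuclei were compared to find the transcripts that part nuclei bearing the neuronal antigen from the rest. Rbfox3, the gene of NeuN itself (chromosome 11, 118351074 to 118772911, mm9), was 2.86 times higher in NeuN+ nuclei (22.3 ± 1.15 against 7.79 ± 0.495 scaled FPKM, mean ± SD, n = 2 each; log2 fold change 1.40, SE 0.06, adjusted p = 2.36e-07). Slc17a6, which encodes a vesicular glutamate transporter (chromosome 7, 58877200 to 58926496), stood at 66.6 ± 0.221 against 0.198 ± 0.0684, and Tac1, a tachykinin precursor (chromosome 6, 7505071 to 7512973), at 319 ± 4.12 against 0.937 ± 0.682. Glial transcripts ran the other way: Gjb6, an astrocyte gap junction protein (chromosome 14, 57742138 to 57752448), was at 0.273 ± 0.100 against 179.8 ± 2.28 and Mbp, a protein of myelin (chromosome 18, 82644515 to 82755029), at 82.1 ± 1.99 against 834 ± 7.41. The long non-coding RNAs Meg3 (chromosome 12, 110779206 to 110809939) and Neat1 (chromosome 19, 5824710 to 5845480) parted in opposite directions, with Meg3 at 1304 ± 0.0730 against 69.9 ± 0.0649 and Neat1 at 0.990 ± 0.0329 against 409.8 ± 1.61.

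Of 13451 genes tested, 11751 passed the threshold in limma, 6138 higher and 5613 lower in NeuN+ nuclei, and 6349 of these differed by at least 2-fold (3423 higher and 2926 lower). The groups did not overlap for 92.4% of the genes, against 33.3% by chance with 2 libraries each. Among the genes with the greatest differences, Matk (104 ± 0.0760 against 0.270 ± 0.188), a tyrosine kinase, Lin7b (104 ± 2.18 against 0.449 ± 0.0157), a synaptic scaffold protein, and Ipw (878 ± 21.3 against 17.6 ± 2.09), an imprinted non-coding RNA, were higher in NeuN+ nuclei. So was 2900055J20Rik (151 ± 5.66 against 0.313 ± 0.316). Cd9, a tetraspanin (1.09 ± 0.326 against 574 ± 18.4), Itih3 (0.272 ± 0.0774 against 163 ± 5.98) and Prkcdbp (0.0788 ± 0.0383 against 137 ± 4.91) were lower. The rule also named AF357425, DQ267100, Mirlet7i and AF357399, whose loci span under 200 bases and whose FPKM is therefore uncertain.

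Non-neuronal gene lists were lower in NeuN+ nuclei. The 19 oligodendrocyte genes and the 18 astrocyte genes were each lower (adjusted p = 7.57e-08, adjusted p = 0.179 with an estimated correlation, and for astrocytes adjusted p = 7.80e-08, adjusted p = 0.179 with an estimated correlation). Myelin and oligodendrocyte genes included Mog (1.71 ± 0.00685 against 195 ± 0.735) and Mal (6.52 ± 0.213 against 353 ± 4.14). Astrocyte genes included Aqp4, a water channel (1.91 ± 0.131 against 96.7 ± 3.17), Aldh1l1 (0.0603 ± 0.0433 against 41.5 ± 0.605) and the glutamate transporter Slc1a3 (11.4 ± 0.741 against 277 ± 9.58; chromosome 15, 8584124 to 8660807). The lists of Bergmann glia (7 of 8 lower; adjusted p = 0.00642), oligodendrocyte precursors (5 of 7; adjusted p = 0.0362) and endothelium (12 of 13; adjusted p = 0.00126) were also lower. So were mural cells (9 of 10; adjusted p = 0.0221), meningeal fibroblasts (6 of 7; adjusted p = 0.00437), choroid plexus and ependyma (6 of 7; adjusted p = 0.0358) and blood (4 of 5; adjusted p = 0.0358). Each of these 7 lists had an adjusted p = 0.179 with an estimated correlation. Examples were Ly6c1 of endothelium (0.218 ± 0.121 against 91.9 ± 3.14), Vtn of mural cells (1.24 ± 0.119 against 307 ± 7.25) and Rarres2 of the choroid plexus list (0.983 ± 0.437 against 159.7 ± 11.2). The microglial list did not pass (adjusted p = 0.0550), with 8 of 15 members lower and 1 higher. Its members C1qb, a complement protein (0.0248 ± 0.0351 against 41.1 ± 0.299), and Ctss, a lysosomal protease (0.0377 ± 0.0534 against 11.02 ± 0.469), were lower.

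Synaptic and channel genes were higher in NeuN+ nuclei. Of 20 presynaptic genes, 17 were higher and 2 lower (adjusted p = 0.00540, adjusted p = 0.179 with an estimated correlation), with Syt1, a calcium sensor of vesicle release, at 68.3 ± 1.54 against 12.2 ± 0.204. Glutamate postsynaptic genes had 13 of 18 higher and 5 lower (adjusted p = 0.0377, adjusted p = 0.179 with an estimated correlation), among them Gria2 (163 ± 2.62 against 25.5 ± 0.0539) and Grik2 (15.4 ± 1.05 against 0.664 ± 0.0535). Voltage-gated channel genes had 15 of 18 higher and 0 lower (adjusted p = 0.00335, adjusted p = 0.179 with an estimated correlation). Nuclear long non-coding RNAs had 8 of 9 higher (adjusted p = 0.0276, adjusted p = 0.180 with an estimated correlation), and Neat1 was the member that was lower.

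Markers of cerebellar neuron types split. The granule neuron list had 11 of 16 genes higher and 4 lower in NeuN+ nuclei and did not pass as a list (adjusted p = 0.0908). Gabra6, a GABA receptor subunit of granule neurons, was at 91.7 ± 0.368 against 30.8 ± 1.96 (chromosome 11, 42119939 to 42134574) and Gabrd at 75.3 ± 1.70 against 2.81 ± 0.132. Of 18 Purkinje cell genes, 12 were lower in NeuN+ nuclei and 6 higher (adjusted p = 0.0656). Pcp2 (162 ± 6.37 against 300.4 ± 4.69; chromosome 8, 3623371 to 3625545) and Calb1 (18.3 ± 0.442 against 53.9 ± 1.27) were lower, while Foxp2 was higher (7.64 ± 0.285 against 0.551 ± 0.00337). The cerebellar interneuron list did not pass either (adjusted p = 0.0689; 8 of 11 higher). In it, Sst, the gene of somatostatin (chromosome 16, 23889667 to 23890930), was 19.7 times higher in NeuN+ nuclei (2370.4 ± 64.8 against 120.2 ± 4.21).

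The lists of DNA methylation genes and histone deacetylases (DNA methylation 9 higher and 7 lower of 18; adjusted p = 0.686, and histone deacetylases 7 and 5 of 17; adjusted p = 0.647) did not pass. Nor did GABA receptors (8 and 5 of 14; adjusted p = 0.339) and immediate early genes (6 and 5 of 11; adjusted p = 0.647). Single members differed widely. Dnmt1, the maintenance DNA methyltransferase (chromosome 9, 20711650 to 20764332), was higher in NeuN+ nuclei (16.2 ± 0.247 against 0.164 ± 0.00100). So were Hdac6 (11.8 ± 0.275 against 0.0827 ± 0.0478), Gabra5 (18.1 ± 0.688 against 0.0305 ± 0.0110), Bdnf, a neurotrophin (11.2 ± 0.638 against 0.0502 ± 0.00638), and Fos (23.8 ± 0.412 against 1.23 ± 0.310). Of 3088 genes over 20 FPKM in homogenate, 74 were under 1 FPKM in both NeuN- libraries, among them Eif3m, and 41 in both NeuN+ libraries. For Dnmt1, Hdac6, Gabra5 and Bdnf, near 0 in NeuN- nuclei, lost transcripts cannot be told apart from lower expression. Gadd45g, of a family linked to DNA demethylation, was lower (11.3 ± 2.36 against 177 ± 8.40). Genes of the respiratory chain were lower (50 of 74 lower and 16 higher; adjusted p = 0.00642, adjusted p = 0.180 with an estimated correlation), with a median of -0.26 on the log2 scale, which became 0.04 with quantile normalization, with 31 genes higher and 28 lower. Ribosomal protein genes were lower too (50 of 78 lower and 15 higher; adjusted p = 0.00335, adjusted p = 0.179 with an estimated correlation), with a median of -0.34, or -0.05 with quantile normalization, with 34 genes higher and 36 lower. The histone deacetylase median changed from 0.12 to -0.04 with that normalization.

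In total 15 of 23 lists passed in camera, 4 higher and 11 lower, and 0 passed with an estimated correlation. Adjusted over the list alone, the counts of members past the threshold were those given, except that 51 respiratory chain genes were lower.

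**Figure D1:**
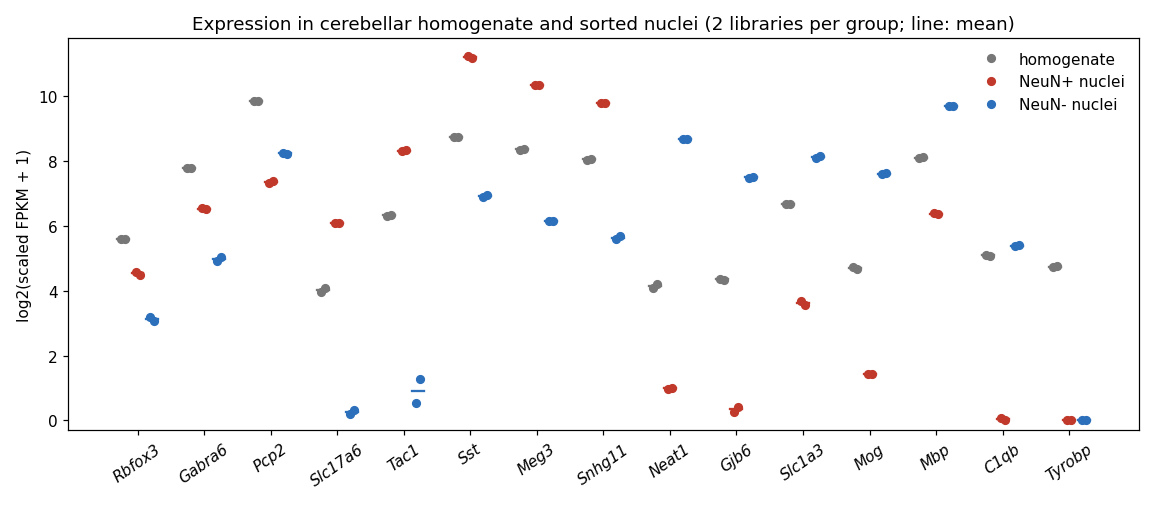
Expression of 15 genes in cerebellar homogenate, NeuN+ nuclei and NeuN- nuclei, on the log2(scaled FPKM + 1) scale; each point is a library, with 2 per group, and the short line is their mean. Slc17a6, Tac1, Sst, Meg3 and Snhg11 lie highest in NeuN+ nuclei, Neat1, Gjb6, Slc1a3, Mog and Mbp in NeuN- nuclei, and Rbfox3, Gabra6 and Pcp2 in homogenate.

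NeuN+ nuclei were also set against whole cerebellar homogenate, which asks how the sorted neuronal nuclei differ from the tissue they came from. Homogenate holds RNA of whole cells. Differences of cell type, of nuclear against whole-cell RNA and of sorting therefore cannot be told apart in this comparison. Rbfox3 was lower in the sorted nuclei than in homogenate (22.3 ± 1.15 against 47.7 ± 0.0909 scaled FPKM, n = 2 each; log2 fold change -1.07, SE 0.06, adjusted p = 2.00e-06), as were Gabra6 (91.7 ± 0.368 against 219.9 ± 2.09) and Pcp2 (162 ± 6.37 against 921 ± 2.81). Higher than in homogenate were Sst (2370.4 ± 64.8 against 429 ± 3.20), Meg3 (1304 ± 0.0730 against 328 ± 2.42) and Miat, another nuclear non-coding RNA (36.1 ± 0.0892 against 7.37 ± 0.174). Ly6c1, an endothelial surface protein (chromosome 15, 74874448 to 74879267), was at 0.218 ± 0.121 against 159 ± 1.40, and Cd9 (chromosome 6, 125410284 to 125444773) at 1.09 ± 0.326 against 111 ± 1.71.

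In limma 11426 of 13451 genes passed, 5362 higher and 6064 lower in NeuN+ nuclei, with 3918 at 2-fold or more. The median log2 fold change of tested genes was -0.05 and moved to -0.32 in the FPKM as deposited, where 33.7% of the calls were higher (3859 higher and 7590 lower) in place of 46.9%. With quantile normalization it was 0.05 and 52.6%. Other genes with the greatest increases were Gm6642 (16.2 ± 0.502 against 0.153 ± 0.0857), 2310002D06Rik (11.9 ± 0.687 against 0.0566 ± 0.0801) and Insl5, an insulin-like peptide (16.2 ± 0.189 against 0.459 ± 0.174). Efcab1 and AA467197 were listed at 0 in both homogenate libraries and stood at 17.4 ± 0.251 and 17.03 ± 0.410 in NeuN+ nuclei. Nuclei are part of the tissue, so increases from a homogenate level at or near 0 are uncertain, and their source was not tested. Among the greatest decreases were Rps4l (0.0866 ± 0.122 against 53.7 ± 2.81) and Id3, a transcriptional regulator (0.605 ± 0.213 against 76.6 ± 1.04), while Crip1 was listed at 0 in both NeuN+ libraries and stood at 47.9 ± 3.39 in homogenate. DQ267100, AF357355, Mirlet7b, Mirlet7d and Mirlet7i, also named by the rule, have loci under 200 bases and uncertain FPKM.

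The 16 granule neuron genes were each lower in NeuN+ nuclei than in homogenate (adjusted p = 9.79e-05, adjusted p = 0.107 with an estimated correlation), with Chn2 at 19.8 ± 0.412 against 74.9 ± 1.64. Of 18 Purkinje cell genes, 16 were lower (adjusted p = 1.25e-04, adjusted p = 0.107 with an estimated correlation). Non-neuronal lists were lower too, among them astrocytes (17 of 18 lower; adjusted p = 2.83e-06, adjusted p = 0.107 with an estimated correlation) and oligodendrocytes (18 of 19; adjusted p = 7.25e-06, adjusted p = 0.107 with an estimated correlation). Microglia (12 of 15; adjusted p = 0.00139, adjusted p = 0.111 with an estimated correlation) and endothelium (13 of 13; adjusted p = 9.79e-05, adjusted p = 0.107 with an estimated correlation) followed. Lower as well were Bergmann glia (8 of 8; adjusted p = 0.00177, adjusted p = 0.111 with an estimated correlation) and mural cells (8 of 10; adjusted p = 0.0132, adjusted p = 0.111 with an estimated correlation). The same held for meningeal fibroblasts (7 of 7; adjusted p = 0.00284, adjusted p = 0.107 with an estimated correlation), choroid plexus and ependyma (7 of 7; adjusted p = 0.00556, adjusted p = 0.111 with an estimated correlation) and blood (5 of 5; adjusted p = 0.00683, adjusted p = 0.111 with an estimated correlation). The haemoglobin gene Hbb-b1 was at 75.4 ± 5.07 against 718 ± 17.9 and Ttr, a choroid plexus protein, at 201 ± 3.46 against 972 ± 5.45. Oligodendrocyte precursor genes did not pass as a list (6 of 7 lower; adjusted p = 0.0573). Respiratory chain genes (70 of 74 lower; adjusted p = 1.36e-12, adjusted p = 0.107 with an estimated correlation) and ribosomal protein genes (72 of 78 lower; adjusted p = 4.59e-11, adjusted p = 0.107 with an estimated correlation) had medians of -0.84 and -0.75 on the log2 scale. These medians were -0.33 and -0.35 with quantile normalization (10 respiratory chain genes higher and 57 lower, 9 ribosomal genes higher and 56 lower) and -1.16 and -1.06 in the FPKM as deposited.

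Histone deacetylase genes were higher in NeuN+ nuclei (15 of 17; adjusted p = 0.00197, adjusted p = 0.107 with an estimated correlation), including Sirt4 (24.4 ± 0.540 against 6.81 ± 0.141) and Hdac1 (11.3 ± 0.666 against 5.18 ± 0.274), and in the FPKM as deposited 10 passed higher and 2 lower. Glutamate postsynaptic genes (15 of 18; adjusted p = 0.00177, adjusted p = 0.107 with an estimated correlation), such as Camk2a (7.13 ± 0.280 against 1.88 ± 0.0173) and Grin2b (10.4 ± 0.270 against 3.08 ± 0.0381), were higher. So were nuclear long non-coding RNAs (8 of 9; adjusted p = 0.00338, adjusted p = 0.112 with an estimated correlation). Presynaptic genes did not pass as a list (14 of 20 lower; adjusted p = 0.0573), but passed lower in the FPKM as deposited (adjusted p = 0.0128, with 1 gene higher and 19 lower). The lists of interneurons (5 of 11 higher; adjusted p = 0.519), DNA methylation (9 of 18; adjusted p = 0.299) and GABA receptors (7 of 14; adjusted p = 0.361) did not pass, and their medians of 0.15, 0.21 and 0.09 became -0.12, -0.05 and -0.23 in the FPKM as deposited. Immediate early genes (2 of 11 higher and 2 lower; adjusted p = 0.856) and voltage-gated channels (8 of 18 higher and 7 lower; adjusted p = 0.445) did not pass. In the FPKM as deposited 1 immediate early gene was higher and 8 were lower, with a median of -0.33 in place of -0.01. The median of the channel list was -0.05, or -0.34 as deposited, while its mean was 0.21 and camera's direction was up. In total 16 of 23 lists passed, 3 higher and 13 lower, and 0 with an estimated correlation. Adjusted over the list alone, the counts of members were the same.

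NeuN- nuclei were set against the same homogenate, where again cell type, nuclear against whole-cell RNA and sorting cannot be told apart. Gjb6, the astrocyte gap junction gene, was 9.28 times higher than in homogenate (179.8 ± 2.28 against 19.4 ± 0.156 scaled FPKM, n = 2 each; log2 fold change 3.15, SE 0.06, adjusted p = 1.73e-08). Neat1 was 24.4 times higher (409.8 ± 1.61 against 16.8 ± 0.946). Mbp (834 ± 7.41 against 275 ± 2.54) and Slc1a3 (277 ± 9.58 against 101 ± 0.802) were also higher. Rbfox3 (7.79 ± 0.495 against 47.7 ± 0.0909), Gabra6 (30.8 ± 1.96 against 219.9 ± 2.09) and Pcp2 (300.4 ± 4.69 against 921 ± 2.81) were lower than in homogenate.

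In limma 11999 of 13451 genes passed, 5390 higher and 6609 lower in NeuN- nuclei, with 5907 at 2-fold or more. The direction of the majority depended on the scaling, with 4450 higher and 7535 lower in the FPKM as deposited and 6093 higher and 5838 lower with quantile normalization. The median log2 fold change was -0.14, and moved to -0.38 in the FPKM as deposited and to 0.03 with quantile normalization. Among the greatest increases were Cd209a, a lectin of myeloid cells (44.9 ± 5.44 against 0.0812 ± 0.115; chromosome 8, 3743395 to 3748984), Bfsp2 (42.7 ± 0.338 against 0.382 ± 0.250) and Srpk3 (49.4 ± 2.53 against 1.06 ± 0.0117). Others were Ccdc151 (24.6 ± 2.28 against 0.0763 ± 0.0342), Zkscan7 (24.5 ± 2.07 against 0.0825 ± 0.00457) and Pstpip2 (27.5 ± 0.0501 against 0.216 ± 0.0787). 2310034G01Rik was listed at 0 in both homogenate libraries against 24.9 ± 0.382. Such increases from a homogenate level at or near 0 are uncertain here too, and their source was not tested. Among the greatest decreases were Apoo (0.0902 ± 0.128 against 60.5 ± 3.04), Avpi1 (0.0974 ± 0.0350 against 51.9 ± 0.472), Tac1 (0.937 ± 0.682 against 79.1 ± 1.15) and Eif3m, a subunit of a translation initiation factor (0.426 ± 0.0168 against 50.0 ± 1.54; chromosome 2, 104839814 to 104857184). S100a11 was listed at 0 in both NeuN- libraries and stood at 39.5 ± 0.400 in homogenate. AF357399, AF357425, Mirlet7d and Gm38671 have loci under 200 bases and uncertain FPKM.

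The 19 oligodendrocyte genes were each higher in NeuN- nuclei (adjusted p = 8.88e-08, adjusted p = 0.147 with an estimated correlation), with Mog at 195 ± 0.735 against 25.0 ± 0.647. Astrocyte genes (16 of 18 higher; adjusted p = 3.88e-05, adjusted p = 0.191 with an estimated correlation) and Bergmann glia genes (7 of 8; adjusted p = 0.0313, adjusted p = 0.311 with an estimated correlation) were higher. Meningeal fibroblast genes (6 of 7; adjusted p = 0.0391, adjusted p = 0.261 with an estimated correlation) were too. The collagen Col3a1 was at 10.6 ± 0.699 against 0.628 ± 0.147. Granule neuron genes were lower (15 of 16; adjusted p = 5.00e-04, adjusted p = 0.147 with an estimated correlation), with Cbln3 at 22.6 ± 0.0778 against 156 ± 4.06, and so were Purkinje cell genes (16 of 18; adjusted p = 0.00197, adjusted p = 0.147 with an estimated correlation). Presynaptic genes (19 of 20 lower; adjusted p = 4.01e-04, adjusted p = 0.147 with an estimated correlation) and voltage-gated channel genes (16 of 18 lower; adjusted p = 0.00197, adjusted p = 0.261 with an estimated correlation) were lower. Syt1 was at 12.2 ± 0.204 against 61.3 ± 0.539 and Kcnc1 at 5.15 ± 0.00559 against 46.2 ± 0.711. Respiratory chain genes (73 of 74 lower; adjusted p = 3.57e-09, adjusted p = 0.147 with an estimated correlation) and ribosomal protein genes (60 of 78 lower and 5 higher; adjusted p = 5.00e-04, adjusted p = 0.147 with an estimated correlation) had medians of -0.65 and -0.37. These were -0.34 and -0.28 with quantile normalization (5 respiratory chain genes higher and 63 lower, 13 ribosomal genes higher and 45 lower) and -0.92 and -0.65 in the FPKM as deposited.

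Microglial genes went both ways (6 of 15 higher and 9 lower; adjusted p = 0.518). Aif1, a calcium-binding protein of microglia, was at 21.5 ± 2.63 against 2.83 ± 0.962, while Tyrobp (chromosome 7, 31198807 to 31202598) and Trem2, partners in microglial signalling, were listed at 0 in both NeuN- libraries and stood at 25.8 ± 0.251 and 7.69 ± 0.112 in homogenate. The lists of endothelium (4 of 13 higher and 6 lower; adjusted p = 0.816) and mural cells (5 and 4 of 10, or 2 and 3 in the FPKM as deposited; adjusted p = 0.529) did not pass. The same held for oligodendrocyte precursors (4 and 2 of 7; adjusted p = 0.226), choroid plexus and ependyma (3 and 4 of 7; adjusted p = 0.845) and blood (0 and 4 of 5; adjusted p = 0.138). Nor did those of interneurons (adjusted p = 0.492), nuclear long non-coding RNA (adjusted p = 0.518), histone deacetylases (adjusted p = 0.492), glutamate postsynaptic genes (adjusted p = 0.350), GABA receptors (adjusted p = 0.506), immediate early genes (adjusted p = 0.518) and DNA methylation (adjusted p = 0.861). For DNA methylation genes camera's direction was up while the median (-0.09, or -0.27 in the FPKM as deposited), the mean (-0.04) and fry were down. Within these lists Dnmt1 (0.164 ± 0.00100 against 6.40 ± 0.432), Hdac6 (0.0827 ± 0.0478 against 5.49 ± 0.189) and Fos (1.23 ± 0.310 against 23.1 ± 0.611) were lower in NeuN- nuclei. Values as near 0 as those of Dnmt1 and Hdac6 do not tell lost transcripts from lower expression. Hdac8 was higher (12.1 ± 1.00 against 1.88 ± 0.0153). In total 10 of 23 lists passed, 4 higher and 6 lower, and 0 with an estimated correlation. Adjusted over the list alone, the counts of members were the same.

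Against the shared homogenate, 2399 genes were higher in both nuclear fractions and 3432 lower in both. Independent lists of these sizes would share 2149 and 2979. Simulated unchanged groups against the same controls shared 0 in each direction over 50 simulations, in which at most 1 gene was called in a comparison. That value leaves out the effects, and the one for independent lists leaves out the shared controls. The 2 homogenate libraries cannot be split further, so part of the excess may come from the shared controls.

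**Figure D2:**
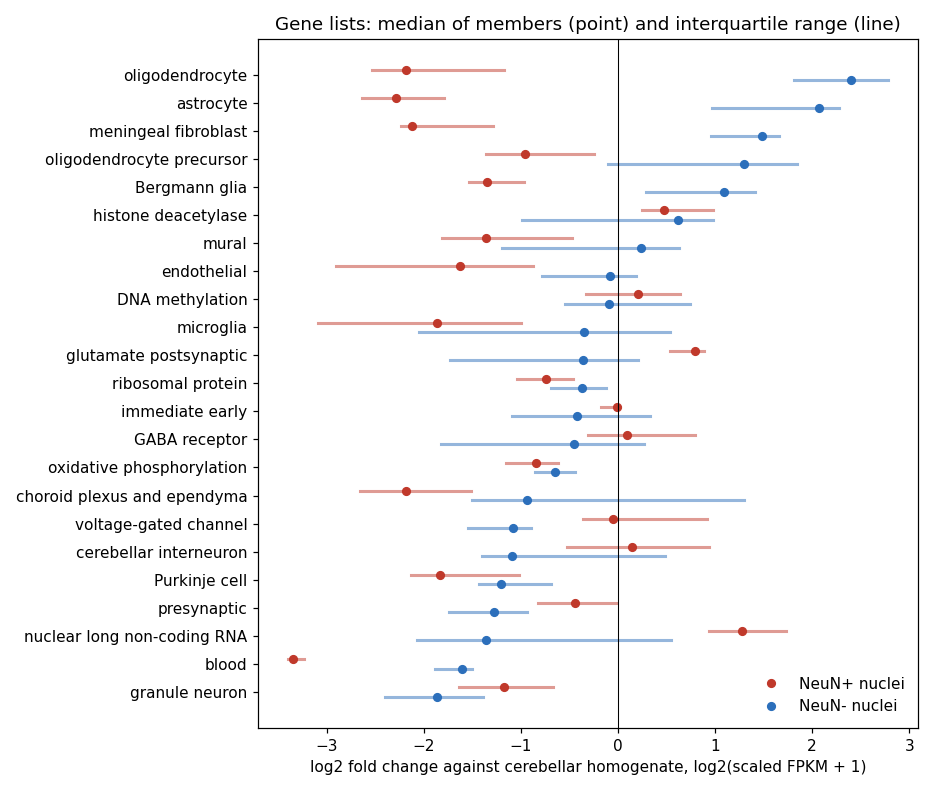
Log2 fold change of 23 gene lists in NeuN+ and NeuN- nuclei against cerebellar homogenate, on the log2(scaled FPKM + 1) scale; points are medians of the members and lines their interquartile range. Oligodendrocyte and astrocyte lists lie above 0 in NeuN- and below 0 in NeuN+ nuclei, while granule neuron, Purkinje cell, respiratory chain and ribosomal protein lists lie below 0 in both.

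NeuN+ nuclei of frontal cortex from clozapine-treated and vehicle-treated mice were compared to find transcripts that differ with the drug. No gene passed the threshold. The haemoglobin gene Hbb-b1, a beta globin (chromosome 7, 110975046 to 110976443), was at 724 ± 272 scaled FPKM with clozapine and 330.3 ± 52.7 with vehicle (mean ± SD, n = 3 each; log2 fold change 1.08, SE 0.26, adjusted p = 0.895), and its 3 clozapine values lay above the 3 vehicle values. Hbb-b2 (chromosome 7, 110961038 to 110962437) was at 426 ± 154 against 191 ± 24.4 and Hba-a1 at 2423 ± 859 against 1335 ± 274. Globin genes are a multigene family whose reads the counting could have split between similar copies, which was not tested, so each value is uncertain. Rbfox3 was at 22.1 ± 5.37 against 20.99 ± 2.08 (log2 fold change 0.05, SE 0.18, adjusted p = 0.963).

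In limma 0 of 12570 genes passed, with 369 at an unadjusted p under 0.05 and a smallest adjusted p of 0.895. Unchanged genes would give a share of 0.05, which is more than 369 of 12570. With the 12 libraries in one fit and the number as a random effect, 0 passed and 584 were at an unadjusted p under 0.05. The groups did not overlap for 11.1% of genes, against 10% by chance. Leaving out each number in turn gave 202 (without vehicle number 2) to 734 genes (without clozapine number 2) at an unadjusted p under 0.05, with 710 without clozapine number 1. With short RNA kept in, 3 genes passed, Mir3065, Mir698 and Snord67, and without vehicle number 1 the short gene AF357399 passed alone. These 4 genes were named after their values were seen. Each was listed at 0 in 1 of the 2 libraries of each number that held it. Mir3065 and Snord67 were listed at 0 in the 6 clozapine libraries, and the vehicle numbers had FPKM of 71.2 and 0, 30.6 and 0, and 36.8 and 0 and of 23.8 and 0, 20.48 and 0, and 24.6 and 0 in their 2 libraries. Mir698 was listed at 0 in the 6 vehicle libraries, and the clozapine numbers had 14.4 and 0, 13.1 and 0, and 0 and 19.2. AF357399 had 47.5 and 0, 43.2 and 0, and 0 and 31.6 with clozapine and 0 and 29.1, 0 and 0, and 0 and 0 with vehicle. The genes with the smallest p, none past the threshold, included Col4a2, a collagen of basement membranes (12.9 ± 1.91 against 6.57 ± 1.07; chromosome 8, 11312829 to 11449287), Fan1, a nuclease of DNA repair (3.59 ± 0.608 against 1.96 ± 0.0721), and Hecw2, a ubiquitin ligase (3.86 ± 0.567 against 2.101 ± 0.323). Lower on average were Grp, gastrin-releasing peptide (13.4 ± 0.877 against 20.4 ± 1.77), and Hmgb3 (15.2 ± 0.215 against 21.7 ± 0.919). The others were H2-Ab1, an antigen-presenting molecule (4.74 ± 0.410 against 7.67 ± 1.35), Tmem114 (1.27 ± 0.108 against 2.33 ± 0.262) and Gm7367 (0.744 ± 0.138 against 1.61 ± 0.0233), each with an adjusted p of 0.895.

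Receptors and chromatin genes linked to antipsychotic action had overlapping values. The serotonin receptor gene Htr2a was at 6.24 ± 3.97 against 5.403 ± 1.02 and the metabotropic glutamate receptor gene Grm2 at 9.42 ± 0.975 against 7.83 ± 1.13. The overlap of Htr2a rests on clozapine number 1, at 1.72. Clozapine numbers 2 and 3 were at 9.15 and 7.85, above the vehicle values of 5.43, 4.37 and 6.41. Hdac2 was at 19.5 ± 2.34 against 19.1 ± 2.77 and Dnmt3a at 6.96 ± 1.87 against 5.29 ± 0.221. Adjusted p for these 4 genes ran from 0.895 to 0.993. Drd2 was below the filter. The list of clozapine target receptors did not pass (adjusted p = 0.834; 7 of 16 higher and 9 lower). Nor did metabotropic glutamate receptors (adjusted p = 0.170), histone deacetylases (adjusted p = 0.300), DNA methylation genes (adjusted p = 0.623), NF-kappaB genes (adjusted p = 0.198) or cholesterol and fatty acid synthesis genes (adjusted p = 0.831).

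Some lists shifted as a whole in camera, though 0 of their members passed singly over the genes tested. The 5 blood genes were each higher on average with clozapine on the log2 scale (median 1.00; adjusted p = 1.30e-05, adjusted p = 0.592 with an estimated correlation), and adjusted over the list alone 3 passed, Hbb-b1, Hbb-b2 and Hba-a1. Hba-a2 overlapped, at 94.9, 28.3 and 52.4 scaled FPKM with clozapine and 4.37, 119 and 46.4 with vehicle. Its rise rests on vehicle number 1. Clozapine number 1 had the highest blood list, 1.27 above the mean of the other numbers on the log2 scale. Of 14 endothelial genes 13 were higher (adjusted p = 7.99e-04, adjusted p = 0.592 with an estimated correlation), with Ly6c1 at 149 ± 51.7 against 98.4 ± 6.68. Voltage-gated channel genes (17 of 19 higher; adjusted p = 7.99e-04, adjusted p = 0.592 with an estimated correlation) and glutamate postsynaptic genes (18 of 21; adjusted p = 0.00260, adjusted p = 0.592 with an estimated correlation) were also higher. So were nuclear long non-coding RNAs (9 of 10; adjusted p = 0.00782, adjusted p = 0.607 with an estimated correlation) and glucocorticoid response genes (8 of 9; adjusted p = 0.00567, adjusted p = 0.592 with an estimated correlation). In them Camk2a was at 62.3 ± 17.6 against 39.6 ± 13.5, Snhg11 at 387 ± 139 against 278 ± 5.74 and Tsc22d3 at 103 ± 6.52 against 91.2 ± 21.1. Lower were immediate early genes (13 of 14; adjusted p = 7.99e-04, adjusted p = 0.592 with an estimated correlation), with Fos at 16.6 ± 3.93 against 27.2 ± 8.33. Respiratory chain genes were lower (65 of 74; adjusted p = 2.12e-04, adjusted p = 0.607 with an estimated correlation), with Atp5b at 1086 ± 269.9 against 1119 ± 85.7. So were microglial genes (11 of 17; adjusted p = 0.0454, adjusted p = 0.592 with an estimated correlation), with Ctss at 71.7 ± 1.477 against 92.1 ± 1.59. The respiratory chain median was -0.11, and 0.01 with quantile normalization. Over the scalings run, the median of 13 of the 32 lists changed sign. Adjusted over the list alone, 0 members passed in lists other than blood.

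The blood, voltage-gated channel and glutamate postsynaptic calls held without each number in turn. Without clozapine number 1 the non-coding RNA (adjusted p = 0.507) and glucocorticoid (adjusted p = 0.0589) calls were lost, and the ribosomal protein list, not called with the 6 numbers (adjusted p = 0.583, median 0.03), turned lower (adjusted p = 2.03e-07). It turned lower also without vehicle number 3 (adjusted p = 2.95e-04), but higher without clozapine number 2 (adjusted p = 0.00523), clozapine number 3 (adjusted p = 0.0135) or vehicle number 2 (adjusted p = 0.00242). Without vehicle number 2 the endothelial (adjusted p = 0.123), respiratory chain (adjusted p = 0.342) and microglial (adjusted p = 0.342) calls were lost. The immediate early call was lost without clozapine number 2 (adjusted p = 0.0726) or vehicle number 1 (adjusted p = 0.173), and the microglial call without clozapine number 2 (adjusted p = 0.152), clozapine number 3 (adjusted p = 0.164) or vehicle number 1 (adjusted p = 0.197). Other lists gained a call. Metabotropic glutamate receptors passed higher without clozapine number 1 (adjusted p = 0.0361) or vehicle number 3 (adjusted p = 0.0372), and GABA receptors higher without clozapine number 1 (adjusted p = 0.0289). Heat shock genes passed lower without clozapine number 2 (adjusted p = 0.00523), excitatory neuron genes higher without vehicle number 2 (adjusted p = 0.0404) and olfactory bulb genes lower without vehicle number 3 (adjusted p = 1.03e-04).

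The other lists of cell markers did not pass. The astrocyte list had 11 of 18 genes lower (adjusted p = 0.592), with Apoe, a lipid carrier, at 5180.4 ± 441 against 5943 ± 249. The oligodendrocyte list had 9 of 16 lower (adjusted p = 0.512), with Mbp at 3666 ± 1709 against 2976 ± 814. The lists of oligodendrocyte precursors (adjusted p = 0.546), mural cells (adjusted p = 0.476), meningeal fibroblasts (adjusted p = 0.546) and choroid plexus and ependyma (adjusted p = 0.886) did not pass. Excitatory neurons (adjusted p = 0.192), upper layers (adjusted p = 0.319) and deep layers (adjusted p = 0.596) did not pass either. The same held for interneurons (adjusted p = 0.448), striatal neurons (adjusted p = 0.881) and olfactory bulb neurons (adjusted p = 0.0749). Slc17a7, a vesicular glutamate transporter, was at 59.7 ± 9.35 against 51.2 ± 11.97 and Sst at 766 ± 51.6 against 975 ± 102. Presynaptic (adjusted p = 0.300), GABA receptor (adjusted p = 0.834), heat shock (adjusted p = 0.170) and circadian (adjusted p = 0.791) genes did not pass. For the meningeal fibroblast list the median (0.01) and the mean (-0.07) differed in sign, for the target receptor list the median (-0.01) and the mean (0.01) did, and for GABA receptors camera's direction was up with a median of -0.02 and a mean of -0.01. In total 9 of 32 lists passed, 6 higher and 3 lower, and 0 passed with an estimated correlation or in fry.

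**Figure D3:**
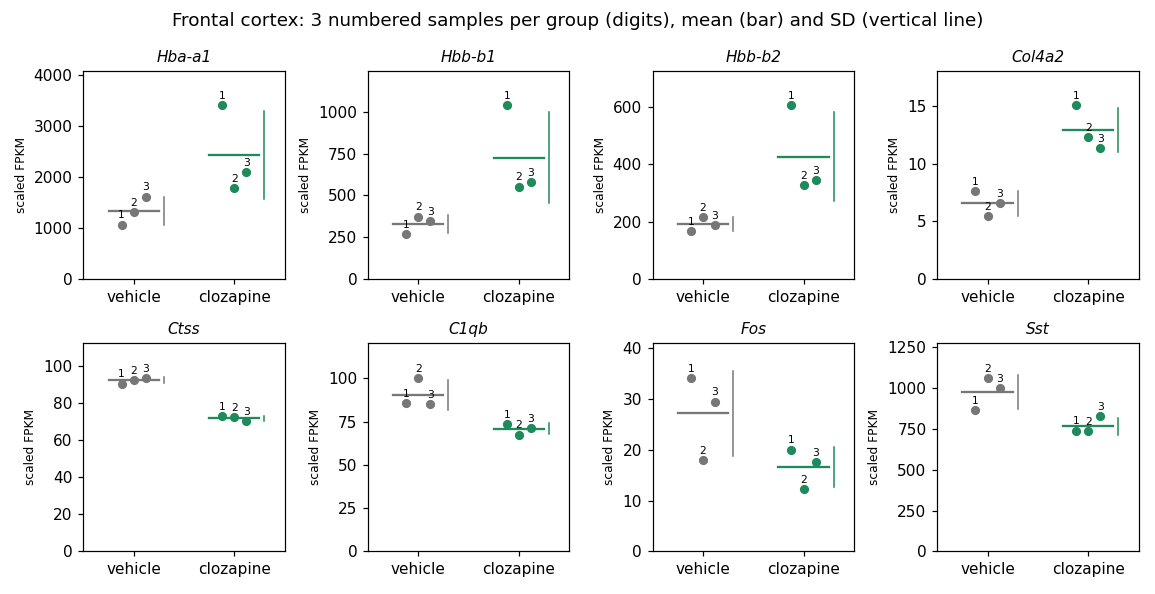
Scaled FPKM of 8 genes in NeuN+ nuclei of frontal cortex given vehicle or clozapine, each axis starting at 0; points are the 3 numbered samples of a treatment with their number, the bar is their mean and the vertical line the SD. Hbb-b1 lies at 330.3 ± 52.7 with vehicle and 724 ± 272 with clozapine, with clozapine number 1 the highest, and no gene passed the threshold over all genes tested.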

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

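The shares below were compared after their values were seen, and no test was run on them. Short RNA genes, left out of the comparisons except in 1 alternative, took 8.03% of summed FPKM in the clozapine libraries on average (6 libraries, 6.99 to 9.86%) against 5.95% with vehicle (4.84 to 6.74%). Clozapine number 1 was at 9.46 and 9.86%, and numbers 2 and 3 at 6.99 to 7.51%, so part of the gap rests on that number. Short RNA genes took 11.2% in NeuN+ cerebellar nuclei and 9.22% in NeuN- nuclei (2 libraries each), against 6.08% in homogenate. Groups of 2 libraries or 3 numbered samples were too small to test for a sample far from the others, and no contrast was repeated in another tissue.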

How the results depend on the processing

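The alternatives were fixed before the data were examined, except that leaving out genes with a locus under 200 bases was chosen after they were seen. In the cerebellum the counts of genes stayed within 1.5 times the values reported in each setting run, with ranges over samples left out in turn of 10842 to 11336 (NeuN+ against NeuN-), 10082 to 11168 (NeuN+ against homogenate) and 10802 to 11658 (NeuN- against homogenate). Where this left 1 library in a group, that library was assumed to vary like the other groups. Of 5453 values of named cerebellar genes under the alternatives, 14 lost their call, for Hbb-bs and Bdnf, and 0 changed sign. For clozapine, 0 genes passed in each setting except 3 with short RNA kept and 0 to 1 with a number left out, a call made without vehicle number 1. These calls rest on 1 of the 2 libraries of a number, with the other listed at 0.

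With an estimated correlation 0 lists passed in each of the 4 comparisons, in a run with little power at these group sizes. fry called 23 of 23 lists for NeuN+ against NeuN-, 22 for NeuN+ against homogenate, 23 for NeuN- against homogenate and 0 for clozapine; it does not compare a list with other genes. camera's direction reversed, without a call, for choroid plexus genes in the FPKM as deposited (adjusted p = 0.988 for NeuN- nuclei, 0.938 for clozapine), and fry's direction differed for DNA methylation genes in NeuN- nuclei against homogenate (adjusted p = 4.74e-04). Over the clozapine and vehicle numbers left out in turn, 7 to 12 lists passed. Lists that reversed in 1 or more of these had adjusted p from 2.03e-07 to 0.169 (ribosomal protein), 0.00523 to 0.812 (heat shock), 0.0289 to 0.816 (GABA receptor), 0.0589 to 0.824 (astrocyte), 0.0589 to 0.816 (target receptor), 0.0589 to 0.988 (meningeal fibroblast), 0.164 to 0.777 (oligodendrocyte), 0.168 to 0.939 (deep layer), 0.219 to 0.777 (cholesterol), 0.260 to 0.705 (choroid plexus), 0.274 to 0.777 (DNA methylation), 0.347 to 0.971 (striatal) and 0.370 to 0.988 (circadian); the cause was not tested.

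With a pseudocount of 0.1 the lowest r between libraries was 0.995 within a cerebellar group, 0.547 between cerebellar groups and 0.988 within a cortical number. With the replicate number as a block (replicate block), 11701, 11382, 11976 and 0 genes passed in the 4 comparisons and the list counts of 15, 16, 10 and 9 were unchanged, though in the cortex the microglial list lost its call (adjusted p = 0.0703) and the olfactory bulb list gained one (adjusted p = 0.0267). No steady pairing by number was seen. Deviations of same-numbered samples correlated at 0.02, -0.01 and 0.05 in the cerebellum and at 0.10, -0.32 and 0.34 in the cortex, where clozapine number 1 correlated best with vehicle number 2 (0.37). This check cannot exclude pairing, because cerebellar deviations were near counting error and clozapine number 1 stood apart in the cortex. Depth limits low genes, and in the simulation of clozapine changes of 0.5 on the log2 scale were not detected.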

Other observations

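The tests of explanations below were chosen after the patterns were seen, and genes outside the naming rule (P2ry12, Lars2, Xist, Ddx3y and Eif2s3y) after their values were. The cortical NeuN+ libraries held abundant RNA of other cell types with either treatment. Apoe ranged from 4503 to 6700 FPKM as deposited over the 12 libraries, Mbp from 2248 to 4757 and C1qb from 61.0 to 106, whereas in cerebellar NeuN+ nuclei Apoe was at 317 and 323, Mbp at 74.7 and 77.7 and C1qb at 0 and 0.0462. The 18 libraries looked alike in sex-linked genes: Xist was at most 0.0808 FPKM, while the Y-linked genes Ddx3y (8.99 to 18.4) and Eif2s3y (43.9 to 59.1) were present throughout.

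In the cortex, 8 of 9 non-neuronal lists had a median ratio to cerebellar homogenate of at least 0.5, against 0 in cerebellar NeuN+ nuclei. RNA of other cells in the sorted material is a candidate source, which the sort for NeuN would have been meant to remove, and region and strain differ too, so this was not tested within 1 tissue. Whole tissue in place of nuclei stays open too. Respiratory chain genes stood at 0.527 times cerebellar homogenate in the cortex. They stood at 0.525 times in cerebellar NeuN- and 0.442 times in cerebellar NeuN+ nuclei. The cortical ratio was thus near that of nuclei, but its reference is another region and strain, so it cannot decide the question.

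Clozapine number 1 stood apart from the other 5 cortical numbers in both of its libraries, with Lars2 at 8220 and 8860 FPKM (1976 to 4221 elsewhere), Hspa8 at 761 and 790 (2232 to 3403), and ribosomal protein and non-coding RNA lists 0.47 and 0.86 higher on the log2 scale. A larger short RNA share would shift other genes by one factor, but the robust SD of its log2 differences after scaling was 0.441 against at most 0.253 in the others. A bias by gene length stays open, because the files hold no transcript lengths (the rank correlation of its differences with locus span, which includes introns, was 0.0152, and up to 0.325 in the others). A lower share of neurons would raise non-neuronal lists alike, yet mural (0.29, error 0.06), astrocyte (0.09, 0.13), endothelial (0.06, 0.16), microglial (-0.02, 0.13) and oligodendrocyte lists (-0.45, 0.18) moved apart, although Mbp was highest in this number (4606 and 4757 FPKM, 2248 to 3907 elsewhere). Blood moved most (1.27, error 0.02). Choroid plexus (0.37) and meningeal fibroblast lists (0.28) were also higher, with oligodendrocyte precursors at -0.04. Each error is the interquartile range over the members of a list, divided by the square root of their number. It treats genes as independent and holds no spread between samples. Whether the lists moved apart beyond that spread was not tested. A response to clozapine cannot be told apart: of the 200 genes farthest from vehicle, 49.5% differed in the same direction in clozapine numbers 2 and 3, but 39.5, 69.5 or 17% did so depending on which vehicle number served as control.

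The 6 numbers make 10 splits into 3 and 3, too few for a share under 0.1. The real split gave 0 genes for clozapine, a count that no split can fall below, and the highest other gave 2. At an unadjusted p under 0.05 in limma, the real split held 369 genes and the others 98 to 1568. The most came with clozapine number 1 beside vehicle numbers 1 and 2. There the groups did not overlap for 21.8% of genes, against 11.1% in the real split.

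Microglial genes parted in cerebellar NeuN- nuclei: as deposited, C1qb was at 39.4 and 39.1 FPKM (homogenate 39.1 and 37.9), while Tyrobp, Trem2 and P2ry12 were listed at 0 in both libraries (homogenate 29.9 and 30.0, 9.05 and 8.78, and 1.82 and 2.103). A changed share of microglia would move these genes by one ratio. The 15 tested genes argue against it as the only cause, since 6 passed higher and 9 lower than homogenate (5 and 9 in the FPKM as deposited). Such a split was not particular to microglia. Of all 13451 genes tested, 5390 passed higher and 6609 lower, and of 13 endothelial genes 4 passed higher and 6 lower. Over the 6 of 17 listed genes at 5 FPKM or more in homogenate, the SD of log2 ratios was 3.82 with 0.1 added to each value (median 1.35 and at most 2.68 in other lists). With 1 added it was 2.17 (median 1.11 and at most 2.61), so whether it was the highest depended on the value added. Few transcripts taken up before the material was divided may account for the parting: of 3088 genes over 20 FPKM in homogenate, 74 were under 1 FPKM in both NeuN- libraries and 16 in 1 alone. That stays open. Of the 149 ribosomal protein and respiratory chain genes among them 0 were lost, but these lists had homogenate medians of 220 and 628 FPKM. Genes so far above 20 FPKM would seldom be lost, so their being kept cannot decide it. A true difference between nuclear and whole-cell RNA was not tested.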
